A study of Homo sapiens with 23 samples.

How the data were processed

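The samples were H1 human pluripotent stem cells (hPSC) and ectoderm, mesoderm and endoderm cells derived from them, taken on day 5 of differentiation, and treated with actinomycin for 0, 1 or 8 h to stop transcription. The series description names actinomycin D and the treatment protocol names actinomycin B, and the files do not settle which was used. RNA was made into libraries with the NEBNext Ultra kit and sequenced on a NovaSeq instrument. The sources used did not state poly(A) selection or rRNA depletion, strandedness or a spike-in. Per the labels, the authors quantified short reads with RSEM and STAR on hg38, with no versions given. The deposited tables held RSEM expected counts per transcript, rounded to whole numbers, and TPM values computed by the authors. They were made on transcripts of an assembly merged over the cell types and, in separate tables, on each cell type's own assembly. The authors' own stability measure was a ratio of log2 TPM at a later time to log2 TPM at 0 h; it was not used here, since it has no error term.

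The labels list 23 samples and the tables hold 20 of them. Mesoderm repeat 3 at each time has no column and was not analysed. That left ectoderm with 2, 2 and 2 libraries at 0, 1 and 8 h, mesoderm with 2, 2 and 2, endoderm with 2, 1 and 2, and hPSC with 1, 1 and 1. The planned design counted 23. The labels do not say whether repeats are separate cultures or separate libraries of 1 culture, so p-values measure only the spread between these samples. They also do not pair repeats across times; correlations of repeat deviations between times ran from −0.095 to 0.25, and repeats were treated as unpaired. No group had 3 libraries, so the test that swaps libraries between groups could not be run. The spread of each pair was compared, which does not show which library of a pair deviates.

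The counts on the merged assembly covered 93365 transcripts, of which 91888 had an Ensembl gene and 31794 also an Ensembl transcript; 1477 had neither gene nor name and were kept as unannotated loci. Counts were summed to 22067 genes and loci, and 17872 passed the edgeR expression filter, 380 of them unannotated loci. Depth ran from 6983535 to 9904912 counts per library, so that 3 counts over the 2 libraries of a group correspond to 0.132 CPM in ectoderm at 0 h and 0.245 CPM at 8 h. TMM factors ran from 0.691 to 1.42. Ribosomal protein genes held 8.2% and 7.55% of counts in ectoderm at 0 h and 13.2% and 15.7% at 8 h, and 8.95% and 18.5% in hPSC. The biological coefficient of variation of the joint fit was 0.176. For repeat pairs it was 0.127, 0.147 and 0.428 in ectoderm at 0, 1 and 8 h, 0.0937, 0.0851 and 0.0886 in mesoderm, and 0.108 and 0.0879 in endoderm at 0 and 8 h. Gene positions came from GENCODE 29, matched for 16904 of the tested genes (94.6%). Genes that overlap on opposite strands, and multi-copy or paralogous genes, can share reads.

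All libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (limma 3.58.1, R 4.3.3, data.table, version 1.17.8) with 1 coefficient per cell type and time and TMM scaling. Comparisons were 1 h and 8 h against 0 h per derived cell type, the 3 differences between cell types in the 8 h change, and the 3 differences between cell types at 0 h. Benjamini-Hochberg adjustment ran over all tested genes per comparison with a threshold of 0.05. Where a group had 0 counts, the fold change was computed with 3 counts in that group and printed as a lower bound. It used counts summed over each group, so it can differ slightly from the ratio of mean CPM to the floor. CPM in the text are counts scaled to the TMM-adjusted library size. hPSC had no test: log2 ratios used a prior count of 2, for genes of at least 10 CPM in the higher library where single genes are named, and lists were placed among 10000 random lists of the same size matched on expression.

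The lists covered immediate early and AU-rich short-lived mRNAs, zinc finger genes (every symbol of ZNF plus digits, with or without a KRAB domain), cytosolic ribosomal proteins, mitochondrial mRNAs, glycolysis, the nuclear-encoded respiratory chain, histones, snoRNA host genes, p53 targets and long noncoding RNAs. They also covered pluripotency genes, HERV-H-linked transcripts, extracellular matrix and secreted proteins, heat shock genes, proteasome subunits, and markers of neuroectoderm, definitive endoderm, mesoderm, trophoblast and amnion, neural crest, and endothelium and blood. Each was tested with camera at an inter-gene correlation of 0.01, adjusted over the 21 lists per comparison; list members are also counted with an adjustment over the list alone. Named genes were the 10 largest changes each way with a symbol, a mean CPM of at least 5 and no overlap between the libraries of the groups, plus up to 4 members per list by adjusted p. Lists, comparisons, tests, the naming rule and the settings to vary were fixed before the data were examined.

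The settings varied by plan were DESeq2 1.42.0 size factors, scaling on ribosomal protein counts, no expression filter, the DESeq2 Wald test, tests on transcripts, leaving out each library, fitting 1 cell type alone, each cell type's own assembly, repeat number as a block, camera with an estimated correlation, fry, and TPM with a pseudocount of 1 or a mean of at least 5 CPM for the agreement of changes. After the data were seen, these were added: a correction for GC content and gene length (a spline with 5 degrees of freedom per library, fitted on protein-coding genes of at least 1 CPM and used as an offset for 16891 genes), voom with a separate variance weight for the ectoderm 8 h pair, fits without that pair, leave-outs for lists and agreement, and the difference in the 1 h change between mesoderm and ectoderm. The planned comparison of transcripts with and without transposable elements was not run, since the tables used hold no such mark.

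The fit was tested on simulated data with 100 changed genes per size and 1 spread per gene for all libraries. The real pairs were not alike in spread (0.428 in ectoderm at 8 h, at most 0.147 in the others). The values below thus do not describe recovery or false calls under that unequal spread. At 2-fold and 4-fold it recovered 50 and 88 for ectoderm at 8 h, 48 and 87 for ectoderm at 1 h, 36 and 92 for mesoderm at 1 h, 19 and 76 for endoderm at 1 h, and 11 and 75 for the difference of mesoderm and ectoderm at 8 h, with 6 to 11 calls among unchanged genes. A GC content and length trend was also simulated, from the same spline model that the correction removes. Calls among unchanged genes then numbered 3279 without the correction and 3 with it, and the 4-fold changes recovered were 70 and 68. This covers a trend of that form only and does not test a bias of another form. Recovery of 2-fold changes fell from 42 to 14 with the correction.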

Results

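Which genes separated the 3 derived cell types before actinomycin was added? The libraries labelled mesoderm held the transcription factor gene POU5F1 at 1610 ± 95 CPM (mean ± SD of TMM-scaled counts, n = 2 libraries), against 31.3 ± 5.7 CPM in ectoderm (n = 2) and 1200 CPM in the single hPSC library. The log2 ratio of mesoderm to ectoderm was 5.68 ± 0.26 (± approximate standard error, adjusted p = 3.02e-10, edgeR quasi-likelihood with Benjamini-Hochberg adjustment, as for all adjusted p of single genes below). That error, here and below, was back-calculated as the absolute log2 change over the square root of the quasi-likelihood F. It is too small where a group holds few counts, as for TDGF1 and NANOG in ectoderm. TDGF1, which encodes a Nodal co-receptor, was higher by 8.77 ± 0.37 (adjusted p = 1.16e-10, 122 against 0.267 CPM), and NANOG by 8.71 ± 0.54 (adjusted p = 1.08e-08, 24.5 CPM against 1 count in the 2 ectoderm libraries together). The neural transcription factor genes FEZF1 (−6.43 ± 0.31, adjusted p = 3.67e-10, 3.49 against 301 ± 40 CPM) and LHX5 (−6.31 ± 0.32) were lower in mesoderm, as was OTX2 (−3.70 ± 0.22). COL1A1 (3.74 ± 0.32, adjusted p = 1.66e-07, 2720 against 203 CPM), COL3A1 (4.93 ± 0.47) and the actin-binding gene TAGLN (3.38 ± 0.31, adjusted p = 2.95e-07) were higher in mesoderm. At 0 h 5039 genes were higher and 6127 lower in mesoderm than in ectoderm, 62.5% of the 17872 tested.

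By the gene lists fixed before the data were examined, 21 of 35 pluripotency genes were higher and 7 lower in mesoderm than in ectoderm (22 and 7 when adjusted over the list alone), with a median log2 ratio of 1.43. LEFTY2 was at least 184-fold higher (0 counts in ectoderm; adjusted p = 3.13e-09) and VRTN higher by 3.46 ± 0.17. All 7 measured HERV-H-linked transcripts were higher (median 3.73), among them ESRG (4.01 ± 0.17, adjusted p = 1.05e-10, 1010 against 62.9 CPM). Of 26 neuroectoderm markers, 3 were higher and 22 lower (median −2.51), and of 439 zinc finger genes named ZNF plus a number 44 were higher and 271 lower (median −1.59; 21 and 158 after correction for GC content and gene length). Mesoderm markers divided into 10 higher and 8 lower of 26 (median 0.47, −0.19 when libraries were scaled on ribosomal protein genes). HAND1 was at 1.21 CPM and PDGFRA at 0.706 CPM in these libraries. Extracellular matrix genes counted 22 higher and 8 lower (median 1.65), definitive endoderm markers 11 and 8, endothelial and blood markers 5 and 3, trophoblast and amnion markers 5 and 5, and neural crest markers 3 and 6.

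Endoderm differed from ectoderm at 0 h in 10031 genes, 4464 higher and 5567 lower (56.1%). CER1, which encodes a secreted Nodal and BMP antagonist, was at least 1160-fold higher (157 ± 47 CPM against 0 counts; adjusted p = 4.07e-10), SOX17 at least 254-fold (33.7 ± 2.4 CPM; adjusted p = 5.66e-07) and GATA4 at least 289-fold (38.6 ± 8 CPM; adjusted p = 6.14e-07). The SOX17 call ended under the DESeq2 Wald test. NODAL was at least 338-fold higher (45 ± 6.3 CPM; adjusted p = 1.9e-09). COL1A1 reached 13100 ± 480 CPM in endoderm (6.01 ± 0.36), COL3A1 was higher by 8.54 ± 0.41, HAND1 by 7.58 ± 0.66 (adjusted p = 2.23e-07, 44.9 CPM), the keratin gene KRT7 by 6.83 ± 0.27 (adjusted p = 3.09e-11) and IGFBP3 by 5.12 ± 0.26 (adjusted p = 3.99e-10). RAX, a gene of the eye field, was lower by 7.82 ± 0.50 (adjusted p = 4.22e-09, ectoderm 153 ± 39 CPM), with FEZF1 (−4.96 ± 0.27) and LHX5 (−4.10 ± 0.26). Neuroectoderm markers as a whole counted 6 higher and 16 lower of 26 (median −1.56), and PAX6 (116 against 82.9 CPM), NES (1240 against 532 CPM) and CDH2 (597 against 285 CPM) stood higher in endoderm. Definitive endoderm markers counted 20 higher and 7 lower of 30 (median 2.98), pluripotency genes 8 and 21 (median −1.73), extracellular matrix genes 28 and 3 (median 2.29), p53 target genes 21 and 2 (median 0.97) and histone genes 11 and 1 (median 1.39). Mesoderm differed from endoderm in 8418 genes (4006 higher, 4412 lower). DNMT3B, a de novo DNA methyltransferase gene, was higher in mesoderm by 4.67 ± 0.14 (adjusted p = 1.41e-11, 610 against 24 CPM) and POU5F1 by 5.84 ± 0.27 (adjusted p = 1.87e-10). CER1 (−4.84 ± 0.25), KRT7 (−2.87 ± 0.20) and IGFBP3 (−6.09 ± 0.28) were lower.

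**Figure D1:**
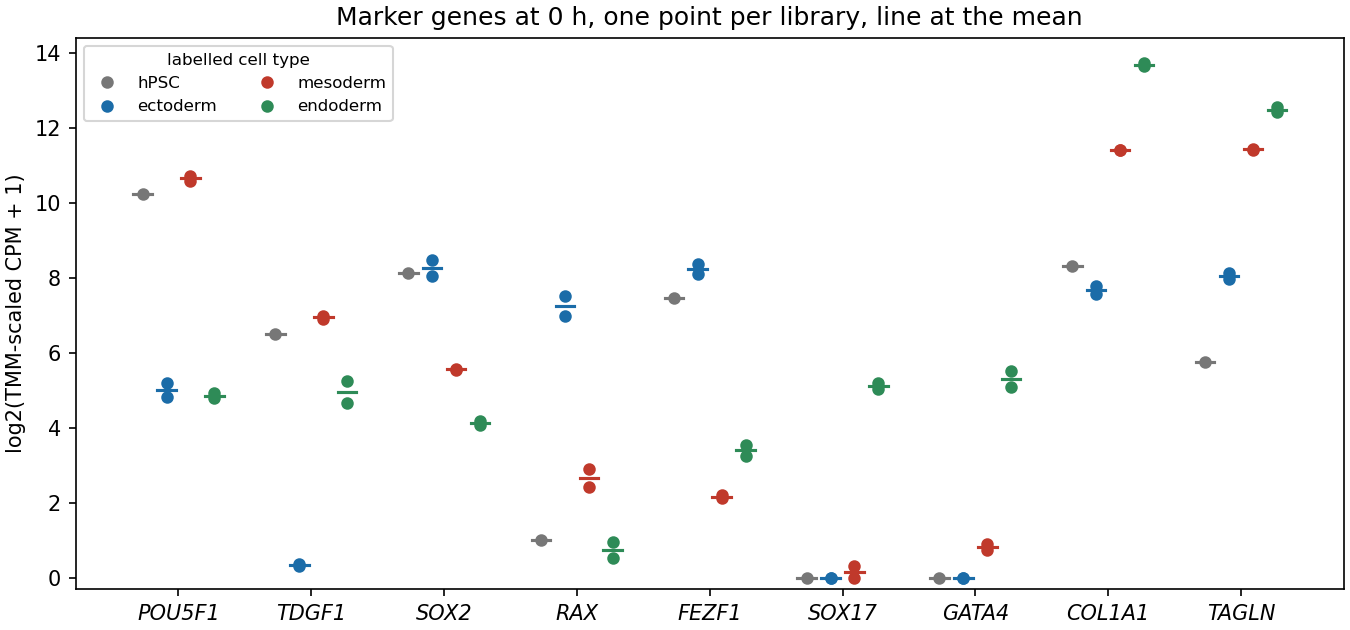
Levels of 9 marker genes before actinomycin in the 4 labelled cell types, 1 point per library and a line at each mean. CPM scaled by TMM, shown as log2 of CPM plus 1.

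The 0 h differences carried a GC content and gene length trend that explained 41.4%, 11.5% and 10.9% of variance over 10750 protein-coding genes (mesoderm to ectoderm, endoderm to ectoderm, mesoderm to endoderm). After correction, 5938 of 10787 mesoderm to ectoderm calls kept their direction and 427 were called the other way. Scaling on ribosomal protein genes turned the splits into 2797 higher and 8239 lower, 5595 and 3513, and 1505 and 9681. Tests on single transcripts called 4365, 3860 and 2595.

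Which RNAs changed within 1 h of actinomycin in mesoderm? JUN, encoding an AP-1 subunit, fell by 2.44 ± 0.21 log2 units (adjusted p = 1.67e-05, 116 to 21.3 CPM, n = 2 and 2). EGR1, an immediate early transcription factor gene, fell by 3.14 ± 0.31 (adjusted p = 5.87e-05, 66.1 to 7.49 CPM), and TRIB1, a pseudokinase gene, by 3.53 ± 0.26 (adjusted p = 5e-06, 59.3 to 5.12 CPM). ADM, which encodes the peptide adrenomedullin, fell by 3.03 ± 0.25 (adjusted p = 1.5e-05, 306 ± 22 to 37.5 ± 3.8 CPM). The mitochondrial 12S rRNA MT-RNR1 (chromosome M, 648 to 1601) rose by 2.98 ± 0.19 (adjusted p = 1.35e-06, 352 ± 9.1 to 2790 ± 180 CPM). In total 1144 genes rose and 276 fell, 7.95% of those tested.

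Of the 47 immediate early and AU-rich mRNAs measured, 1 rose and 18 fell at 1 h in mesoderm (2 and 27 over the list alone; median −0.66). DUSP1 (−2.32 ± 0.22) and HES1 (−3.03 ± 0.41, adjusted p = 0.000447) were among those that fell. CSRNP1, which is not on the list, fell by 3.12 ± 0.35. The list lay lower than all other genes by camera (adjusted p over 21 lists = 4.31e-16; adjusted p = 0.0105 with an estimated correlation). Ribosomal protein genes counted 14 up and 0 down (17 and 0 over the list alone; median 0.26), with RPL7 at 1.40 ± 0.15 (adjusted p = 9.67e-05) and RPL5 at 0.77 ± 0.11. After GC and length correction 6 were up and 2 down. Respiratory chain genes counted 11 and 0. Proteasome subunits counted 9 and 0 (PSMD14 1.56 ± 0.26, a call that ended without mesoderm 0 h repeat 1). There were 5 and 0 among heat shock genes (HSPD1 1.32 ± 0.14, adjusted p = 9.88e-05) and 6 and 0 among extracellular matrix genes (FSTL1 0.98 ± 0.12, LAMC1 0.81 ± 0.13). After GC and length correction these counted 3 and 1 for the respiratory chain, 4 and 0 for the proteasome, 3 and 0 for heat shock genes and 4 and 1 for extracellular matrix genes. Without the ectoderm 8 h pair, the respiratory chain counted 12 and 3, and 10 and 10 with the correction too. In the same 2 fits glycolysis genes counted 2 and 6, then 3 and 4, and mitochondrial mRNAs 0 and 3, then 0 and 10. Zinc finger genes counted 7 up and 27 down (ZNF574 −1.76 ± 0.29, adjusted p = 0.00138). The p53 targets counted 3 and 3 (CCNG1 1.46 ± 0.15, SESN2 −1.08 ± 0.15, CDKN1A −0.94 ± 0.13) and snoRNA host genes 2 and 4 (SNHG3 −1.07 ± 0.19, adjusted p = 0.00226). The nuclear RNA MALAT1 fell by 1.47 ± 0.25 (adjusted p = 0.00199), one of 3 falls and 0 rises among long noncoding RNAs. Pluripotency genes counted 2 and 3 (PODXL 0.75 ± 0.15), neuroectoderm markers 1 and 3, glycolysis genes 2 and 0 (LDHB 1.09 ± 0.16), and mitochondrial mRNAs 0 and 1 (MT-ND2 −0.91 ± 0.26, adjusted p = 0.0398). The calls for PODXL and MT-ND2 ended under ribosomal protein scaling.

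Camera also placed ribosomal proteins higher (adjusted p = 0.000119; adjusted p = 0.725 with an estimated correlation), heat shock genes higher (adjusted p = 0.00167; adjusted p = 0.248 with an estimated correlation) and zinc finger genes lower (adjusted p = 0.00219; adjusted p = 0.725 with an estimated correlation). Among the genes with the largest rises were SNX6 (1.90 ± 0.20, adjusted p = 9.88e-05) and COPS4 (2.04 ± 0.23, adjusted p = 0.000159). The count of 1420 was not stable: it was 299 without mesoderm 0 h repeat 1, 621 without 0 h repeat 2, 384 without 1 h repeat 1 and 464 without 1 h repeat 2. GC content and length explained 22.7% of variance in the 1 h change, and 777 genes were called after correction (461 up, 316 down). The split of 80.6% up was 351 up to 181 down under ribosomal protein scaling and 731 to 370 under DESeq2 size factors. It was 2260 to 1665 with mesoderm libraries alone.

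Was the early response detectable in ectoderm and endoderm? In ectoderm (n = 2 and 2) 1 gene rose and 5 fell at 1 h. JUN fell by 1.91 ± 0.24 (adjusted p = 0.0139, 12.8 ± 1.4 to 3.39 ± 0.89 CPM) and MT-RNR1 rose by 1.28 ± 0.18 (adjusted p = 0.0194, 283 ± 45 to 688 CPM), a call that ended under ribosomal protein scaling (1.23 ± 0.25, adjusted p = 0.319) as its spread grew. SNORA11E, a small nucleolar RNA (chromosome X, 52063347 to 52063474), fell by 2.64 ± 0.40 (adjusted p = 0.0318) and the pseudogene WASH8P, whose reads are shared with its paralogs, by 0.80 ± 0.13 (adjusted p = 0.0478, 93.8 to 53.9 CPM). SNORA8 (chromosome 11, 93732361 to 93732499; −8.63, adjusted p = 0.0194) and ENSG00000283189 (chromosome 3, 49416777 to 49429314; −7.39, adjusted p = 0.0318) also fell, and are named here only because they completed the count of 6, a choice made after the values were seen. GC content and length explained 39.9% of variance in the ectoderm 1 h change. After GC and length correction 5 genes were called, 0 higher and 5 lower, 3 of them shared. The MT-RNR1 call thus ended there too. The immediate early list counted 0 rises and 1 fall (0 and 13 over the list alone; median −0.47; camera adjusted p = 3.26e-13, adjusted p = 0.02 with an estimated correlation). snoRNA host genes had 0 calls (0 and 5 over the list alone; camera adjusted p = 0.000557, adjusted p = 0.156 with an estimated correlation). An unadjusted p under 0.05 was reached by 1678 genes. The count of 6 became 2 without ectoderm 0 h repeat 1 and 0 without 0 h repeat 2 or without 1 h repeat 2. With repeat number as a block the count was 0. It was also 0 when the ectoderm libraries were fitted alone or on their own assembly, so the JUN call ended there too (−1.95 and −1.94, adjusted p over 0.9).

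Endoderm at 1 h was a single library, assumed to vary like the other groups, and 0 genes passed, while 1288 had an unadjusted p under 0.05. Other settings called 31 (DESeq2 Wald), 76 (voom with a separate variance weight for the ectoderm 8 h pair), 9 (GC and length correction), 331 (endoderm libraries alone) and 21 (no expression filter). DUSP6, a MAP kinase phosphatase gene, stood at −1.61 ± 0.28 (adjusted p = 0.24, 79.5 ± 5.2 to 26 CPM) and MALAT1 at −2.19 ± 0.31 (adjusted p = 0.0686), neither past the threshold. Over the list alone, 10 immediate early mRNAs fell and 0 rose (median −0.39; camera adjusted p = 1.38e-07, adjusted p = 0.0907 with an estimated correlation), and 2 long noncoding RNAs fell.

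The joint fit estimates 1 spread for all libraries, and the 2 ectoderm 8 h libraries differed from each other more than any other pair. The 1 h tests shared that spread. Without those 2 libraries, an alternative added after the data were seen, 700 genes were called in ectoderm at 1 h (491 up, 209 down), 3175 in mesoderm (1671 up, 1504 down) and 329 in endoderm (19 up, 310 down). With GC and length correction as well, these were 145 (54 up, 91 down), 1901 (1113 up, 788 down) and 279 (151 up, 128 down). The immediate early list counted 0 rises and 12 falls in ectoderm, 2 and 29 in mesoderm, and 0 and 14 in endoderm, where 1 h is 1 library and its spread is borrowed from the other groups. In that fit ZFP36L2 (−0.78 ± 0.12, adjusted p = 0.00307), IER3 (−1.10 ± 0.19, adjusted p = 0.0047) and HES1 (−1.39 ± 0.25, adjusted p = 0.00554) fell in ectoderm. DUSP6 (−1.69 ± 0.21, adjusted p = 0.000689), JUN (−1.01 ± 0.19, adjusted p = 0.00783) and MALAT1 (−2.26 ± 0.25, adjusted p = 0.00033) passed in endoderm only if that single library varied like the others.

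**Figure D2:**
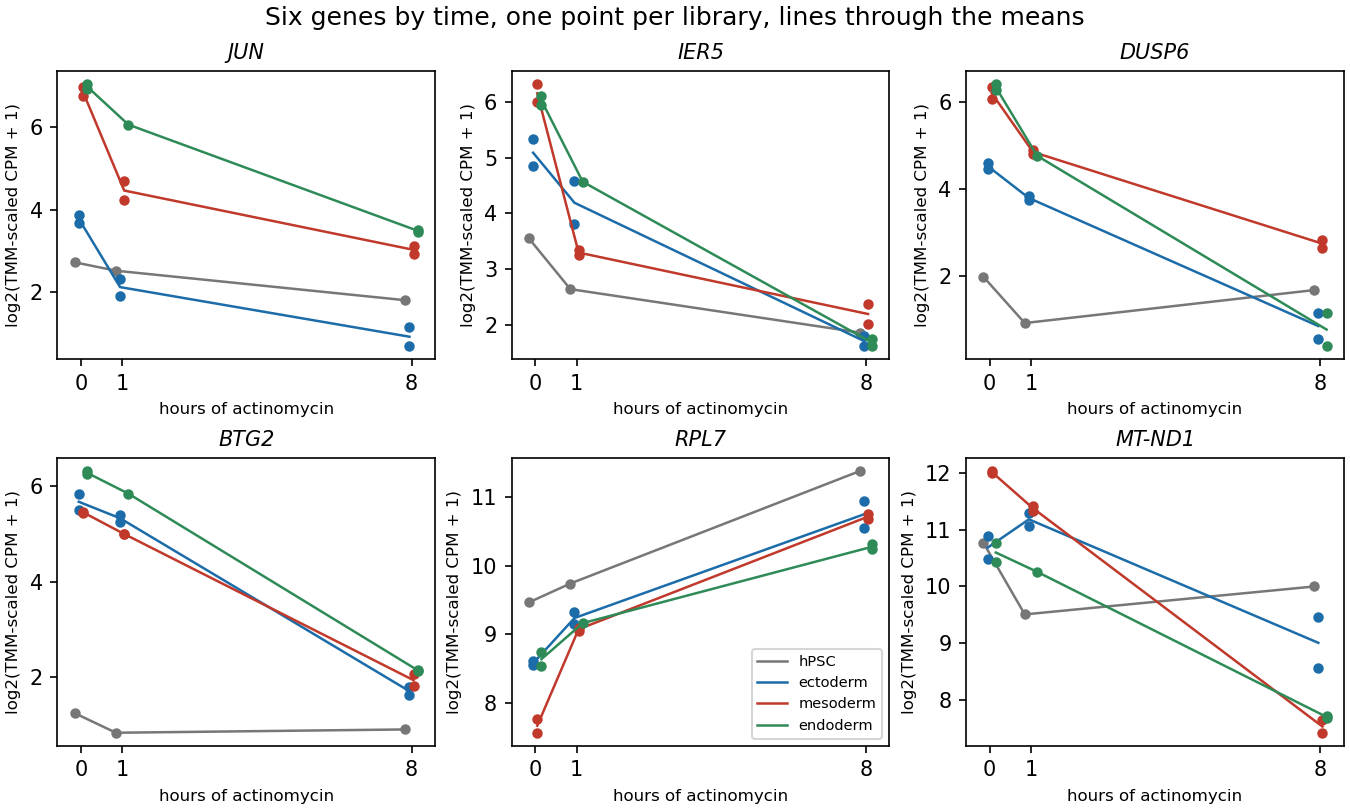
Levels of 6 genes over 8 h of actinomycin in the 4 labelled cell types, 1 point per library with lines through the means. CPM scaled by TMM, shown as log2 of CPM plus 1.

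Which RNAs changed over 8 h in ectoderm? GRHL3, an epithelial transcription factor gene, fell at least 142-fold (34.5 ± 4.2 CPM, 794 counts, to 0 counts; adjusted p = 1.64e-07, n = 2 and 2). The homeobox gene DLX5 fell by 5.77 ± 0.46 (adjusted p = 1.22e-07), the Notch target HES1 by 5.84 ± 0.58 (adjusted p = 7.95e-07) and the adhesion scaffold gene NEDD9 by 5.64 ± 0.36. CDKN1A, which encodes the cell cycle inhibitor p21, fell by 4.26 ± 0.18 (adjusted p = 7.06e-10, 69.1 to 3.62 CPM). MT-RNR1 rose by 4.07 ± 0.20 (adjusted p = 2.2e-09, 283 ± 45 to 4770 ± 1600 CPM) and ATP5F1E, an ATP synthase subunit gene, by 2.95 ± 0.26 (adjusted p = 3.02e-07). In total 3870 genes rose and 4867 fell, 48.9% of those tested, 2409 and 4061 of them more than 2-fold.

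All of these are changes relative to the other RNAs of a library. The sources used stated no spike-in, and without one a rise can mean a slower loss than the rest. The median over all tested genes moved by −1.55 in ectoderm, −0.35 in mesoderm and −0.68 in endoderm at 8 h when libraries were scaled on ribosomal protein genes in place of TMM, and by 0.16, −0.15 and 0.02 with DESeq2 size factors. Under ribosomal protein scaling ectoderm counted 129 rises and 12445 falls, and after GC and length correction 5125 and 4066. Ribosomal protein scaling fixes the summed share of those genes, so their own medians under it lie near 0 by construction in every comparison. Those medians do not test whether ribosomal protein genes rose. In each 0 h and 8 h comparison of this report the side with more calls turned in at least 1 setting, so no split is read as more genes on 1 side.

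Among immediate early and AU-rich mRNAs in ectoderm at 8 h, 1 rose and 43 fell of 47 (1 and 44 over the list alone; median −2.96), including BTG2 (−4.46 ± 0.22, adjusted p = 2.73e-09), ZFP36L2 (−3.90 ± 0.19, adjusted p = 2.14e-09) and CCN1 (−2.98 ± 0.17). Zinc finger genes counted 9 rises and 223 falls (median −1.12; ZNF672 −4.08 ± 0.23, adjusted p = 7.83e-09; ZNF581 −3.39 ± 0.21). Ribosomal protein genes counted 77 and 0 of 79 (median 1.71, 0.07 under ribosomal protein scaling), with RPL22 at 2.25 ± 0.15 (adjusted p = 2.11e-08), RPL7 at 2.18 ± 0.15 and RPL6 at 1.75 ± 0.12, the last call ending under that scaling. The 0.07 follows from scaling on these same genes, and neither it nor the end of the RPL6 call tests their rise. Respiratory chain genes counted 59 and 3 (median 1.28, −0.31 under ribosomal protein scaling). Glycolysis genes counted 15 and 3 (median 1.31, then −0.31), with PGK1 at 1.60 ± 0.12, ENO2 at 1.65 ± 0.13 and SLC2A1 at −2.05 ± 0.17. Extracellular matrix genes counted 30 and 0 of 33 (median 1.47, then −0.1; NID1 1.71 ± 0.12, LAMC1 1.73 ± 0.13). The p53 targets counted 4 and 22 (median −1.51; SESN2 −3.94 ± 0.22, AEN −2.70 ± 0.16). Proteasome subunits counted 19 and 9 (PSMC6 −2.48 ± 0.31) and heat shock genes 8 and 4, with DNAJB1 falling by 3.95 ± 0.19 (adjusted p = 2.14e-09) and HSP90AA1 rising by 1.54 ± 0.17 (adjusted p = 1.94e-06; −0.02 under ribosomal protein scaling).

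The remaining lists in ectoderm were mixed or small. Pluripotency genes counted 6 rises and 14 falls (ZFP42 −3.05 ± 0.18, MYCN −3.37 ± 0.26). Neuroectoderm markers counted 5 and 18, and OTX2 fell by 3.14 ± 0.21 (195 ± 16 to 22 ± 8 CPM), SIX3 by 3.15 ± 0.25, LHX5 by 3.12 ± 0.25 and ZIC2 by 3.50 ± 0.21. HERV-H-linked transcripts counted 0 and 3 (LINC00678 −2.81 ± 0.18, ESRG −1.56 ± 0.17) and snoRNA host genes 11 and 11 (GAS5 1.65 ± 0.12, SNHG6 2.74 ± 0.23, SNHG3 −2.25 ± 0.20). Mitochondrial mRNAs counted 1 rise and 5 falls, MT-ND1 falling by 1.63 ± 0.23 and MT-ND2 by 1.91 ± 0.26 (adjusted p = 2.01e-05), while MT-CO1 rose by 1.08 ± 0.21 (adjusted p = 0.000506; −0.43 under ribosomal protein scaling). Definitive endoderm markers counted 4 and 12, mesoderm markers 3 and 9, trophoblast and amnion markers 2 and 7, neural crest markers 2 and 4. There were 4 and 1 among endothelial and blood markers, 4 and 2 among histone genes (H1-2 2.17 ± 0.38) and 4 and 4 among long noncoding RNAs (NORAD −1.36 ± 0.18). Camera placed the immediate early list lower (adjusted p = 1.1e-16; adjusted p = 0.0103 with an estimated correlation) and p53 targets lower (adjusted p = 6.2e-05; adjusted p = 0.0191 with an estimated correlation). It placed ribosomal proteins higher (adjusted p = 9.13e-32; adjusted p = 0.185 with an estimated correlation) and extracellular matrix genes higher (adjusted p = 1.1e-16; adjusted p = 0.0638 with an estimated correlation). Proteasome subunits were placed higher (adjusted p = 0.0284) and, under ribosomal protein scaling, lower (adjusted p = 0.00173). With an estimated correlation the first call was lost (adjusted p = 0.559). Voom with a separate variance weight for this pair called 5044 genes, and 3998 single transcripts passed.

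Which RNAs changed over 8 h in mesoderm? HPS6, a gene for the biogenesis of lysosome-related organelles, fell by 6.82 ± 0.43 log2 units (adjusted p = 6.02e-09, n = 2 and 2) and TENT5B, encoding a nucleotidyltransferase, by 6.27 ± 0.32 (adjusted p = 1.08e-09). CCN1, a matricellular protein gene, fell by 4.51 ± 0.17 (adjusted p = 1.66e-10, 650 ± 46 to 28.6 CPM). EFEMP1, which encodes the matrix protein fibulin-3, rose by 3.93 ± 0.20 (adjusted p = 1.25e-09, 6.19 to 94.5 CPM), and FBN2, encoding fibrillin-2, by 3.33 ± 0.14 (adjusted p = 4.6e-10, 72.7 to 732 ± 63 CPM). MT-ND1 (chromosome M, 3307 to 4262) fell by 4.49 ± 0.26 (adjusted p = 2.36e-09, 4130 ± 66 to 184 ± 20 CPM) while MT-RNR1 rose by 3.44 ± 0.19 (adjusted p = 2.13e-09). In total 4176 genes rose and 3923 fell, 45.3% of those tested, 3200 and 2924 of them more than 2-fold.

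In mesoderm at 8 h, 1 immediate early mRNA rose and 41 fell (median −2.96): RHOB by 5.03 ± 0.24 (adjusted p = 8.4e-10), MYC by 4.24 ± 0.24 (adjusted p = 1.99e-09), BTG2 by 3.90 ± 0.21 and HES1 by 5.76 ± 0.54. All 13 mitochondrial mRNAs fell (median −2.53; MT-ND2 −4.85 ± 0.30, adjusted p = 4.71e-09). Extracellular matrix genes counted 25 rises and 0 falls (median 1.55, 1.19 under ribosomal protein scaling; COL3A1 2.80 ± 0.27, LAMC1 2.74 ± 0.13). Ribosomal proteins counted 40 and 2 (median 0.4, then 0.04; RPL7 3.05 ± 0.15, RPL22 2.34 ± 0.15) and respiratory chain genes 24 and 8 (median 0.17, then −0.19; NDUFB5 2.38 ± 0.23). Proteasome subunits counted 11 and 1 (median 0.19, then −0.17; PSMA4 1.99 ± 0.16) and heat shock genes 9 and 4 (HSP90AA1 3.28 ± 0.18, adjusted p = 1.66e-09; DNAJB1 −3.46 ± 0.17, adjusted p = 1.08e-09). Zinc finger genes counted 21 and 141 (median −0.54; ZNF581 −4.11 ± 0.18, ZNF687 −2.96 ± 0.14) and p53 targets 7 and 14 (SESN2 −4.02 ± 0.18, CCNG1 2.55 ± 0.16). Pluripotency genes counted 6 and 16 (median −0.79), and VRTN fell by 4.90 ± 0.19 (adjusted p = 2.95e-10, 286 to 9.54 CPM), MYCN by 4.62 ± 0.26 and ZFP42 by 2.84 ± 0.18. Glycolysis genes counted 6 and 6 (LDHB 2.03 ± 0.16, SLC2A1 −1.06 ± 0.16), neuroectoderm markers 5 and 12 (SOX3 −4.44 ± 0.29, NCAM1 3.84 ± 0.26) and definitive endoderm markers 5 and 9 (CPE 3.51 ± 0.19).

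The smaller lists in mesoderm at 8 h counted 8 rises and 7 falls for mesoderm markers, 9 and 6 for snoRNA host genes (SNHG3 −2.57 ± 0.20), 8 and 2 for long noncoding RNAs (NEAT1 2.52 ± 0.24). They counted 4 and 5 for trophoblast and amnion markers, 2 and 3 for neural crest, 1 and 1 for endothelial and blood markers, 3 and 0 for histones, and 0 and 2 for HERV-H-linked transcripts. Other large falls were RPUSD2 (−6.05 ± 0.46) and PARS2 (−5.95 ± 0.43), and other large rises SULF1 (4.01 ± 0.34), ELOVL2 (4.55 ± 0.50) and ADAMTS18 (4.53 ± 0.48). Camera placed the immediate early list lower (adjusted p = 1.07e-17; adjusted p = 0.00764 with an estimated correlation), mitochondrial mRNAs lower (adjusted p = 1.45e-07; adjusted p = 0.317 with an estimated correlation) and extracellular matrix genes higher (adjusted p = 1.08e-11; adjusted p = 0.225 with an estimated correlation). GC content and length explained 22.7% of variance, and 5880 of 7899 calls kept their direction after correction while 35 were called the other way. The split became 2815 up and 5279 down under ribosomal protein scaling, and 2987 single transcripts passed.

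Which RNAs changed over 8 h in endoderm? DUSP6 fell by 6.72 ± 0.35 (adjusted p = 6.41e-09, 79.5 to 0.759 CPM, n = 2 and 2) and DUSP1, a second MAP kinase phosphatase gene, by 6.47 ± 0.24 (adjusted p = 3.04e-10, 241 to 2.73 CPM). CXCR4, encoding a chemokine receptor used as an endoderm marker, fell by 5.02 ± 0.41 (adjusted p = 3.44e-07, 50.8 to 1.53 CPM), and the forkhead gene FOXC2 by 5.94 ± 0.32 (adjusted p = 1.71e-08). ANXA1, encoding annexin A1, rose by 2.23 ± 0.20 (adjusted p = 6.82e-07, 96.5 to 451 CPM) and FSTL1, encoding a secreted glycoprotein, by 1.54 ± 0.12 (764 to 2230 CPM). In total 3089 genes rose and 2994 fell, 34% of those tested, 1378 and 2325 of them more than 2-fold.

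Immediate early mRNAs in endoderm counted 1 rise and 42 falls at 8 h (1 and 44 over the list alone; median −2.82), including RHOB (−5.11 ± 0.24, adjusted p = 4.27e-09), BTG2 (−4.48 ± 0.21) and CCN1 (−3.21 ± 0.16). IER5L (−6.23 ± 0.52), TRIB1 (−5.55 ± 0.33) and NUAK2 (−5.44 ± 0.29) also fell. Definitive endoderm markers counted 3 rises and 15 falls (median −1.84). Pluripotency genes counted 3 and 13, with LEFTY1 at −2.67 ± 0.24 (adjusted p = 1.16e-06, 114 to 17.9 CPM) and MYCN at −3.65 ± 0.35. Neuroectoderm markers counted 4 and 12 (OTX2 −2.14 ± 0.22) and zinc finger genes 6 and 178 (median −1.09; ZNF672 −3.16 ± 0.21). Mitochondrial mRNAs counted 0 and 8 (median −1.21), MT-ND1 falling by 2.91 ± 0.24 (adjusted p = 3.47e-07, 1560 ± 250 to 206 CPM) and MT-ND2 by 3.37 ± 0.28. The p53 targets counted 6 and 15 (AEN −2.11 ± 0.15, PLK2 −2.66 ± 0.20). Ribosomal proteins counted 64 and 0 (median 0.72, 0.02 under ribosomal protein scaling; RPL7 1.64 ± 0.15) and extracellular matrix genes 29 and 0 (median 0.96, then 0.25; NID1 1.27 ± 0.12). Respiratory chain genes counted 33 and 2 (median 0.59, then −0.11; ATP5PF 1.09 ± 0.15, a call that ended) and glycolysis genes 10 and 1 (median 0.45, then −0.26; LDHB 1.21 ± 0.16). Proteasome subunits counted 12 and 1 (median 0.36, then −0.35; PSMA4 1.24 ± 0.16) and heat shock genes 9 and 2 (HSPD1 1.58 ± 0.14, DNAJB1 −2.12 ± 0.16). The other lists counted 7 and 5 for mesoderm markers (SNAI2 −4.37 ± 0.47, HAND1 −2.60 ± 0.46), 7 and 2 for snoRNA host genes (median 0.3, then −0.4; GAS5 0.73 ± 0.12), 5 and 3 for long noncoding RNAs (NEAT1 1.87 ± 0.24). They counted 4 and 0 for histones, 1 and 5 for trophoblast and amnion markers, 2 and 3 for neural crest, 3 and 1 for endothelial and blood markers, and 1 and 1 for HERV-H-linked transcripts.

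Other rises in endoderm included MT-RNR1 (3.01 ± 0.19, adjusted p = 3.3e-08, 295 to 2380 CPM), CPS1 (2.19 ± 0.19) and SRP9 (2.13 ± 0.17, adjusted p = 2.21e-07). Camera placed the immediate early list lower (adjusted p = 4.62e-24; adjusted p = 0.00264 with an estimated correlation), definitive endoderm markers lower (adjusted p = 0.000454; adjusted p = 0.0789 with an estimated correlation) and extracellular matrix genes higher (adjusted p = 1.43e-13; adjusted p = 0.097 with an estimated correlation). Glycolysis genes (adjusted p = 0.000626) and proteasome subunits (adjusted p = 0.00183) were placed higher, and under ribosomal protein scaling lay lower without passing (adjusted p = 0.798 and 0.786). With an estimated correlation both calls were lost (adjusted p = 0.426 and 0.455). That scaling gave 476 rises and 5996 falls, and 1456 single transcripts passed.

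**Figure D3:**
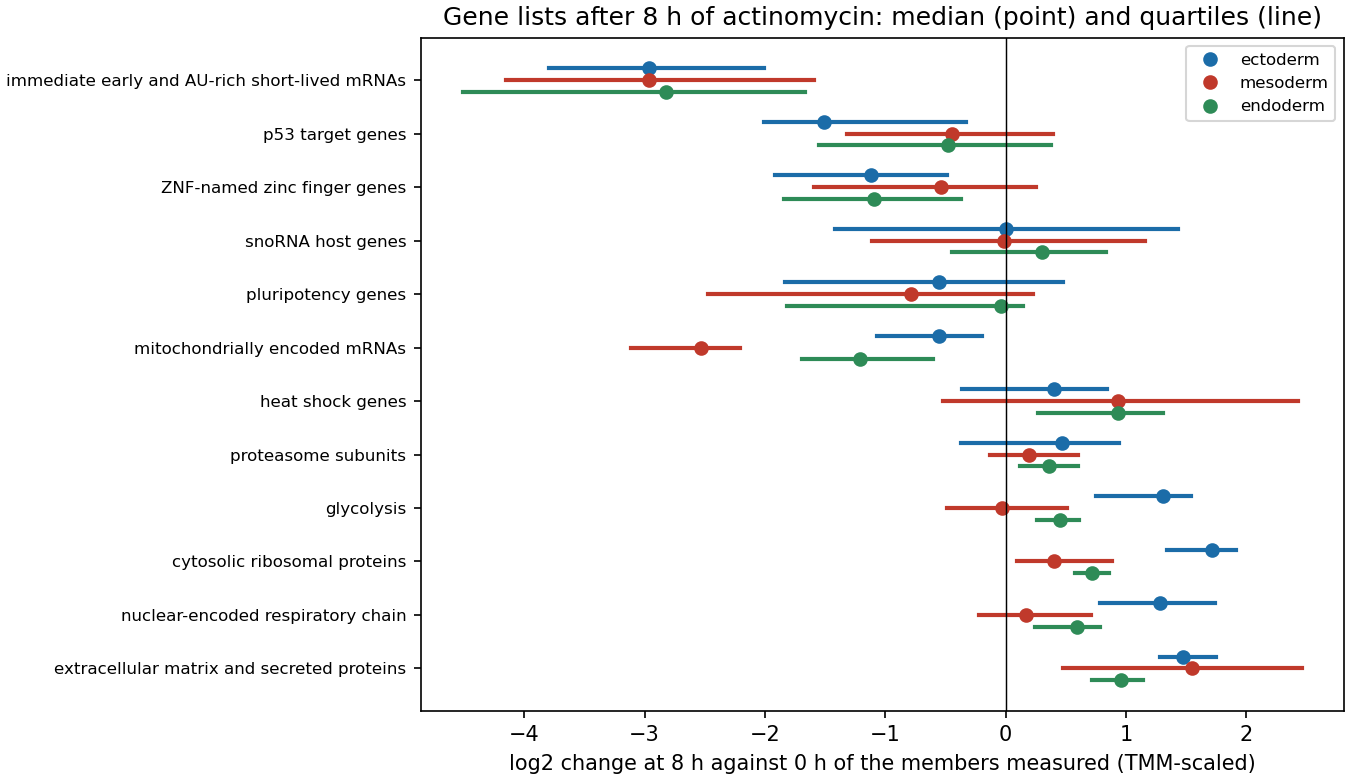
Log2 change after 8 h of actinomycin for 12 gene lists fixed before the data were examined, with the median as a point and the quartiles as a line, by labelled cell type. TMM scaling.

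Did the 8 h change differ between cell types? For mesoderm minus ectoderm the test of the difference called 6475 genes, 3841 higher and 2634 lower (36.2%). CDKN1A went from 281 to 111 CPM in mesoderm and from 69.1 to 3.62 CPM in ectoderm, a difference of 2.92 ± 0.22 (adjusted p = 1.35e-06, n = 2 per group). FBN2 rose further in mesoderm (2.35 ± 0.19, adjusted p = 1.37e-06), as did the chaperonin gene HSPD1 (2.23 ± 0.20, adjusted p = 2.47e-06). MT-ND1 fell further in mesoderm (−2.86 ± 0.32, adjusted p = 1.45e-05). LEF1, a Wnt effector gene, went from 0.24 to 1.89 CPM in mesoderm and from 17 to 2.29 CPM in ectoderm (5.77 ± 0.88, adjusted p = 0.000157), and ZNF521 differed by 3.87 ± 0.38 (adjusted p = 5.72e-06).

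By list, mesoderm minus ectoderm was lower for 54 ribosomal protein genes and higher for 2 (median −1.07, 0.15 under ribosomal protein scaling; RPSA −1.85 ± 0.22). It was lower for 40 respiratory chain genes and higher for 8 (median −0.97, then 0.29), and lower for 12 glycolysis genes and higher for 4 (PGK1 −1.26 ± 0.17, ending under that scaling; ALDOC −2.49 ± 0.26). Mitochondrial mRNAs counted 0 higher and 12 lower (median −1.96; MT-ND2 −2.94 ± 0.37; camera adjusted p = 8.23e-08, adjusted p = 0.419 with an estimated correlation). The p53 targets counted 16 and 2 (median 1.00; camera adjusted p = 0.00326, adjusted p = 0.145 with an estimated correlation). Zinc finger genes counted 58 and 31 (median 0.47, −0.29 after GC and length correction). Immediate early mRNAs counted 10 and 9 (ZFP36L2 1.88 ± 0.25, CCN2 1.75 ± 0.24, CCN1 −1.53 ± 0.23, the last ending under ribosomal protein scaling) and extracellular matrix genes 12 and 11 (FBN1 2.24 ± 0.24, LAMB1 1.37 ± 0.18). Neuroectoderm markers counted 10 and 1, mesoderm markers 10 and 3, pluripotency genes 3 and 7 (VRTN −2.52 ± 0.29; DNMT3B −1.52 ± 0.17, ending under that scaling) and HERV-H-linked transcripts 2 and 0 (LINC00678 2.36 ± 0.23). C1QL1 (−3.39 ± 0.53) and TUBB4A (−3.18 ± 0.33) were among the largest negative differences. GC content and length explained 45% of variance in this difference, and 3998 genes were called after correction (1725 higher, 2273 lower). Of 6394 earlier calls with both values 2729 kept their direction and 32 were called the other way. The split was 2925 higher and 3626 lower under DESeq2 size factors and 8300 and 200 under ribosomal protein scaling, and 1339 single transcripts passed.

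For endoderm minus ectoderm 3239 genes differed, 1907 higher and 1332 lower (18.1%). CCN2, which encodes connective tissue growth factor, went from 5270 to 3620 CPM in endoderm and from 64.7 to 4.74 CPM in ectoderm (3.21 ± 0.24, adjusted p = 4.33e-06). CDKN1A differed by 3.41 ± 0.22 (adjusted p = 1.78e-06) and the glucose transporter gene SLC2A1 by 2.30 ± 0.23 (adjusted p = 2.54e-05). SMAD7, an inhibitor of TGF-β signalling, was lower by 4.50 ± 0.50 (adjusted p = 4.73e-05, 64 to 3.98 CPM in endoderm, 3.32 to 4.77 CPM in ectoderm), and DUSP1 by 3.51 ± 0.54. METRNL (4.80 ± 0.50) and FZD8 (3.37 ± 0.48) were higher, though both calls ended with the separate variance weight for the ectoderm 8 h pair. The p53 targets counted 12 higher and 0 lower (median 0.57; TNFRSF10B 1.73 ± 0.17; camera adjusted p = 0.000947, adjusted p = 0.0875 with an estimated correlation). HERV-H-linked transcripts counted 3 and 0 (LINC00678 2.31 ± 0.26), heat shock genes 7 and 1, and ribosomal proteins 0 and 47 (median −0.92, −0.02 under ribosomal protein scaling). Respiratory chain genes counted 3 and 22 (median −0.76, then 0.18), glycolysis genes 2 and 12 (median −0.74, then 0.14), extracellular matrix genes 0 and 10 (median −0.52, then 0.35; COL6A2 −1.82 ± 0.24) and immediate early mRNAs 10 and 10. The snoRNA host GAS5 was lower by 0.92 ± 0.17, a call that ended under ribosomal protein scaling, which gave 5553 genes higher and 83 lower. The count was 1909 without ectoderm 0 h repeat 2, 1844 without endoderm 0 h repeat 2 and 292 for single transcripts. Lower genes outnumbered higher ones without ectoderm 8 h repeat 1 (2315 higher, 3220 lower) or 2 (1825 and 2390) and without endoderm 8 h repeat 1 (993 and 1360) or 2 (997 and 1135). The same held with the separate variance weight (640 and 866), GC and length correction (1512 and 1942), no filter (1449 and 2006), the Wald test (1603 and 1867) and DESeq2 size factors (1619 and 1647).

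For mesoderm minus endoderm 2189 genes differed, 1444 higher and 745 lower (12.2%). FBN2 rose further in mesoderm (2.16 ± 0.19, adjusted p = 4.54e-05), as did the laminin gene LAMB1 (1.89 ± 0.18), the adhesion molecule gene NCAM1 (2.47 ± 0.34, adjusted p = 0.000607) and CPE (1.89 ± 0.24). DUSP6 fell less in mesoderm (3.05 ± 0.47), CCND1 differed by 1.24 ± 0.23, and SNAI2, which fell in endoderm, by 4.46 ± 0.74 (adjusted p = 0.00205). EOMES differed by 5.42 ± 1.19 (adjusted p = 0.00947), from 4 to 10 counts in mesoderm and 225 to 10 in endoderm, and that call ended without mesoderm 8 h repeat 1. The growth factor gene PDGFB (−2.68 ± 0.32, adjusted p = 0.00035), TMEM186 (−4.20 ± 0.56), SESN2 (−1.63 ± 0.24), SLC2A1 (−1.30 ± 0.23) and MT-CYB (−2.51 ± 0.35, adjusted p = 0.000709) were lower. Mitochondrial mRNAs counted 0 higher and 8 lower (median −1.2; camera adjusted p = 4.92e-07, adjusted p = 0.429 with an estimated correlation) and extracellular matrix genes 14 and 0 (median 0.45; camera adjusted p = 0.000122, adjusted p = 0.605 with an estimated correlation). Respiratory chain genes counted 4 higher and 1 lower although their median was −0.35 and camera placed them lower (adjusted p = 0.0212; adjusted p = 0.805 with an estimated correlation). Ribosomal proteins counted 6 and 4 (median −0.31, 0.04 under ribosomal protein scaling). The count was 1076 without mesoderm 0 h repeat 1, 1185 without mesoderm 8 h repeat 2, 1066 without endoderm 0 h repeat 1, and 1219 and 1442 without endoderm 8 h repeat 1 or 2. GC and length correction left 1338 genes (639 higher, 699 lower), voom with the separate variance weight called 4292, 99 single transcripts passed, and the fit without the ectoderm 8 h pair called 4859. The split was 988 higher and 1274 lower under DESeq2 size factors and 1751 and 210 under ribosomal protein scaling.

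Was the 1 h fall larger in mesoderm than in ectoderm? This comparison was added after the values were seen. It called 19 genes, 12 higher and 7 lower, with 1861 at an unadjusted p under 0.05. TRIB1 (−2.66 ± 0.34, adjusted p = 0.0168, 59.3 to 5.12 CPM in mesoderm, 32.1 to 17.5 CPM in ectoderm), EGR1 (−2.43 ± 0.41, adjusted p = 0.0381), FOS (−3.26 ± 0.58, adjusted p = 0.0467), IER5 (−2.10 ± 0.36, adjusted p = 0.0431), DUSP1 (−1.88 ± 0.30, adjusted p = 0.0381), the kinase gene NUAK2 (−1.93 ± 0.31, adjusted p = 0.0381) and ADM (−2.13 ± 0.38, adjusted p = 0.0491) made up the 7 lower genes. AMOT (1.79 ± 0.29), COPS4 (1.78 ± 0.30), NRDC (1.30 ± 0.20), COPB2 (1.17 ± 0.19) and SCRN1 (1.05 ± 0.19) were among the 12 higher. The immediate early list counted 0 higher and 4 lower (0 and 12 over the list alone; camera adjusted p = 6.94e-05, adjusted p = 0.315 with an estimated correlation). The call count was 1 under ribosomal protein scaling, 12 (5 higher, 7 lower) under DESeq2 size factors and 0 with repeat number as a block. It was 650 without the ectoderm 8 h pair (329 higher, 321 lower), 695 with GC and length correction as well, and 519 with the voom weight. Leaving out 1 library gave 8 (ectoderm 0 h repeat 1), 1 (ectoderm 0 h repeat 2 or mesoderm 0 h repeat 2), 2 (mesoderm 0 h repeat 1 or 1 h repeat 2) and 0 (ectoderm 1 h repeat 1 or 2, or mesoderm 1 h repeat 1).

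How far did the cell types share the 8 h change? Across 17872 genes the log2 changes correlated with Pearson r = 0.423 (Spearman 0.44) for mesoderm and ectoderm, 0.45 (0.531) for endoderm and ectoderm, and 0.502 (0.587) for mesoderm and endoderm. Single-library pairs ranged from 0.346 to 0.524, 0.466 to 0.538 and 0.543 to 0.61. For genes with a mean of at least 5 CPM in every derived cell type, r was higher (0.59, 0.725 and 0.826). Genes called lower in both numbered 2464, 2299 and 2130, where independence gives 1068, 815 and 657. Genes called higher in both numbered 1786, 1981 and 2355 (904, 669 and 722 under independence), and opposite calls 771, 260 and 65 (1987, 1490 and 1378). All 3 cell types shared 1478 rises and 1783 falls, or 2831 and 1815 after GC and length correction. Under ribosomal protein scaling ectoderm had only 129 rises, so no more than 129 could be shared there.

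What changed in hPSC? Each time was 1 library, so no test was made and the values below are ratios of single libraries. At 1 h, 117 of 9714 genes lay more than 2-fold higher and 278 lower (196 in total after GC and length correction), and at 8 h 2479 and 3355 of 10169. MT-RNR1 stood at 20800 CPM at 8 h against 386 CPM at 0 h (log2 ratio 5.75), NDUFA1 at 4.23, ABHD12B at 4.26, SLC16A3 at 3.99 and JAG2 at 3.96. POU3F1 had 0 counts against 655, PIGC 0 against 187, B3GNT2 3 against 571 (−6.29) and KIF20B 5 against 576 (−5.78). At 1 h the phosphatase gene PTP4A2 had 35 counts against 416 (−3.38), SNORD116-23 0 against 119, SNORA8 a ratio of −3.44, and FKBP2 and RN7SL2 ratios of 2.56 and 2.01. Against 10000 random lists matched on expression, the immediate early list had a median of −0.69 at 1 h (random −0.11, percentile 0) and −1.32 at 8 h (random −0.47, percentile 0.46). It was not alone at 1 h: mitochondrial mRNAs had −1.03 (random 0.17, percentile 0) and zinc finger genes −0.39 (random −0.15, percentile 0). Neuroectoderm markers had −0.5 (random −0.04, percentile 0.16), long noncoding RNAs −0.47 (random −0.04, percentile 0.23) and respiratory chain genes 0.3 (random 0.1, percentile 100). At 8 h zinc finger genes had −1.61 (random −0.6, percentile 0), p53 targets −1.34 (random −0.53, percentile 1.8) and pluripotency genes −0.64 (random 0.44, percentile 0). Neuroectoderm markers had −1.18 (random −0.3, percentile 0.7), mitochondrial mRNAs −0.66 (random 1.22, percentile 0) and heat shock genes −0.17 (random 0.77, percentile 1.44). Ribosomal proteins had 1.97 (random 1.27), respiratory chain genes 1.62 (random 0.46), extracellular matrix genes 1.75 (random 0.55) and histones 0.81 (random −0.7), at percentile 100 each. Glycolysis genes had 1.65 (random 1.07, percentile 99.7). Random lists at the level of ribosomal protein or glycolysis genes thus rose too, and the rises of those 2 lists are only partly their own. The 8 h ratios of hPSC correlated at r = 0.63 with the changes of ectoderm, 0.373 with mesoderm and 0.446 with endoderm. These r were taken without GC correction. Spearman correlation with GC content was 0.18, −0.5 and −0.18 for the 3 changes in the same order. For the hPSC libraries, each against the mean of all libraries, it was −0.44 at 0 h and −0.084 at 8 h. The order of the 3 r may follow these trends, which was not tested.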

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

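The tests below on the share of calls left by the GC content and length correction (42.7%), on the share left without 1 ectoderm 8 h library (84.4%) and on the resemblance of mesoderm to hPSC (3.56 and 0.811) were chosen only after the results were seen; the others were written down before they were run.

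The tests of the difference called 6475 genes for mesoderm minus ectoderm, 3239 for endoderm minus ectoderm and 2189 for mesoderm minus endoderm at 8 h, and 19 for mesoderm minus ectoderm at 1 h. For the first, 42.7% of the called genes kept their call and direction after correction. A library bias of the spline form that the correction removes thus does not account for the whole. A GC content or length bias of another form could leave calls standing and was not tested. For the 3633 genes whose call ended, the median absolute log2 difference went from 1.43 to 0.41 and the median back-calculated standard error from 0.34 to 0.29. Their calls ended because the differences shrank. The outcome written down for a bias was thus met, but choosing genes by the end of their call makes it nearly certain, so it was not counted for the bias. For these genes a library bias and decay that itself follows GC content cannot be told apart, since the correction removes both. One of the 2 unlike ectoderm 8 h libraries as the whole cause was examined by leaving either out. At least 84.4% of the called genes kept their call and direction. This cannot decide, since leaving out either library also removes the pair with the widest spread from the shared estimate of spread. That favours keeping calls whatever the cause. This share was chosen after a planned sign test was dropped, because a call nearly fixes its outcome. A fault that both libraries shared is not tested by it.

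The libraries labelled mesoderm held POU5F1, NANOG and TDGF1 at the level of hPSC or above. Most of the pluripotency list stood lower than in the single hPSC library. Among these were SOX2 (46 against 279 CPM), DNMT3B (610 against 1510 CPM) and LIN28A (868 against 2040 CPM). Others stood higher, such as VRTN (286 against 165 CPM) and UTF1 (32.7 against 11.5 CPM). Undifferentiated cells like those of the hPSC library, mixed in at 1 share, would scale all hPSC-specific genes alike only if the other cells lacked them. The log2 ratio of mesoderm to hPSC over 37 such genes had an interquartile range of 3.56 after GC and length correction. It ran from SEMA3E at 1.88 and LRRTM4 at 1.10 to CUZD1 at −5.26 and CYP26C1 at −5.55. These genes were chosen against ectoderm and endoderm, with no condition on mesoderm. Expression in the other cells would widen the ratios too, so the spread cannot exclude such a share. A share that alone gave POU5F1 its ratio of 0.28 would keep the rest near hPSC level, but the lower quartile was −3.9. A wrong label on libraries like that hPSC library was not favoured: the highest Spearman correlation with the hPSC library was 0.811, against 0.986 to 0.988 between repeats. Both checks were first run without the correction and had the same outcome. The 1 hPSC library held FEZF1 at 176, LHX5 at 111 and OTX2 at 198 CPM (301, 120 and 195 CPM in ectoderm), with NODAL at 0 and LEFTY1 at 0.0919 CPM, and it correlated more with ectoderm (up to 0.859) than with mesoderm. The ratios and the 0.811 therefore speak only to cells like that library. A smaller share of such cells, or undifferentiated cells of another state, could still explain a part or all of the pattern.

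The 2 ectoderm 8 h libraries differed from each other with an SD of log2 differences of 0.875, against 0.412 and 0.503 in the other 8 h pairs. Whether 1 library had gone further along the 8 h change could not be decided. The library difference had Pearson r = 0.063 with the mean change of mesoderm and endoderm, under the bound set against this. But r was taken without GC correction, and the GC trends of the 2 sides were opposite. Spearman correlation with GC content was 0.58 for the library difference, −0.5 for the mesoderm change and −0.18 for the endoderm change (protein-coding genes). A GC content or length bias of 1 library could account for a part: these explained 39.9% of the variance, and the SD over 10503 protein-coding genes went from 0.832 to 0.645 on their removal. A library of another cell type under a wrong label is not favoured, since repeat 2 was closer to repeat 1 than to any other cell type at 8 h by 0.057 in Spearman correlation. The bias test does not separate library preparation from RNA quality.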

How the results depend on the processing

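The GC content and length correction, the voom weight, the fits without the ectoderm 8 h pair and the leave-outs of lists and agreement were chosen only after the results were seen. Values are numbers of genes called unless stated, and the cause of a move was not tested. For genes named in this report, 3385 of 3608 results under alternatives stayed, 197 became weaker (123 of them in leave-outs), 24 stronger and 2 reversed. Most of these genes were named for large changes or small adjusted p, which favours staying. The share thus does not describe all calls. For lists called by camera, 158 of 264 results stayed, 103 became weaker and 3 reversed.

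Ectoderm 1 h (6 genes) gave 0 with repeats as a block, 0 with ectoderm libraries alone, 0 on its own assembly, 72 with the DESeq2 Wald test, 1311 with the voom weight, 700 without the ectoderm 8 h pair and 145 with GC correction as well; leave-outs gave 0 to 4. Mesoderm 1 h (1420) gave 532 under ribosomal protein scaling, 3925 with mesoderm libraries alone, 3946 on its own assembly, 3175 without the pair, 89 for transcripts, 2790 with the voom weight and 777 with GC correction; leave-outs gave 299 to 621. Endoderm 1 h (0) gave 1 with DESeq2 size factors, 21 without a filter, 331 alone, 305 on its own assembly, 329 without the pair, 279 with GC correction as well, 13 for transcripts, 31 with Wald, 76 with the voom weight and 9 with GC correction. Transcripts numbered 3998, 2987 and 1456 at 8 h in ectoderm, mesoderm and endoderm, and 4365, 3860 and 2595 in the 0 h differences; the voom weight gave 5044 in ectoderm at 8 h.

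Mesoderm minus ectoderm at 8 h (6475) gave 1339 for transcripts and 3998 with GC correction. Endoderm minus ectoderm (3239) gave 5636 under ribosomal protein scaling, 292 for transcripts and 1506 with the voom weight; leave-outs gave 1844 to 5535. Mesoderm minus endoderm (2189) gave 4859 without the pair, 99 for transcripts, 4292 with the voom weight and 1338 with GC correction; leave-outs gave 1066 to 1634. The 1 h difference (19) gave 12 with DESeq2 size factors, 1 under ribosomal protein scaling, 38 without a filter, 0 with a block, 650 without the pair, 695 with GC correction as well, 4 for transcripts, 137 with Wald, 519 with the voom weight and 36 with GC correction; leave-outs gave 0 to 8. With repeats as a block the other counts were 8304, 1049, 7605 and 5548 within ectoderm (8 h), mesoderm (1 h, 8 h) and endoderm (8 h), 0 for endoderm at 1 h, and 5935, 2507 and 1605 for the 3 differences.

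Camera called 66 of 189 combinations of a list and a comparison, so that 1 list can count more than once. An estimated correlation left 6, fry gave 81 (44 shared), ribosomal protein scaling 63 (49 shared) and GC correction 77 (59 shared). Of the named genes and camera calls, 5 in ectoderm and endoderm at 8 h turned sign under ribosomal protein scaling, apart from list medians that turned: MT-CO1 (−0.43, adjusted p = 0.183), HSP90AA1 (−0.02, adjusted p = 0.961), proteasome subunits in ectoderm (adjusted p = 0.00173, lower) and in endoderm (0.786, lower), and glycolysis in endoderm (0.798, lower). The agreement of mesoderm and ectoderm, endoderm and ectoderm, and mesoderm and endoderm was r = 0.497, 0.626 and 0.734 on TPM, 0.59, 0.725 and 0.826 at a mean of at least 5 CPM, and 0.523, 0.491 and 0.538 with GC correction; leave-outs gave 0.348 to 0.421, 0.387 to 0.438 and 0.443 to 0.486. In hPSC at 1 h GC correction left 196 genes past 2-fold. On simulated data 11 of 100 2-fold differences between mesoderm and ectoderm and 19 of 100 2-fold changes in endoderm at 1 h were recovered, so uncalled genes there are not shown to be unchanged. The 6 alternatives planned for transposable element transcripts were not run, since no mark of them is in the tables used.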

Other observations

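The exon test (−1.71) was chosen only after the results were seen; the test on unannotated loci (−0.16) was written down before it was run.

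The 12S rRNA of mitochondria rose in share at 8 h, and the 16S rRNA rose less and in ectoderm not under every scaling, while 5, 13 and 8 of 13 mRNAs of the same genome fell in ectoderm, mesoderm and endoderm and 1, MT-CO1 in ectoderm, rose (TMM scaling). At 8 h MT-RNR1 rose by 4.07 ± 0.20 in ectoderm, 3.44 ± 0.19 in mesoderm and 3.01 ± 0.19 in endoderm, and MT-RNR2 by 1.54 ± 0.18 (adjusted p = 4.4e-06), 1.03 ± 0.18 (adjusted p = 0.000192) and 1.75 ± 0.18 (adjusted p = 3.24e-06). Under ribosomal protein scaling MT-RNR1 rose by 2.56 ± 0.26, 3.08 ± 0.27 and 2.30 ± 0.26. MT-RNR2 was then at 0.01 ± 0.24 in ectoderm (adjusted p = 0.989), where its call ended because the change went to 0, 0.67 ± 0.24 in mesoderm (adjusted p = 0.0333) and 1.03 ± 0.24 in endoderm (adjusted p = 0.00354). The 99th percentile of protein-coding genes lay at 2.1, 3.01 and 1.69 in the same comparisons under TMM.

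Intronless genes fell further than others. The median 8 h change of single-exon protein-coding genes was −1.86 in ectoderm (127 genes), −2.4 in mesoderm (129) and −1.38 in endoderm (132, all genes of at least 5 CPM), against −0.01, 0.05 and 0.18 for genes with more exons. Genes with 2 to 4 exons lay between (−0.8, −0.65 and −0.21). Of the single-exon genes 93, 105 and 83 were called lower and 10, 8 and 5 higher. The smallest difference over the 3 cell types, adjusted for length, GC content and 0 h level, was −1.71. This met the outcome written down for the hypothesis that fewer exons mark less stable mRNA, but it is the same difference after adjustment, so it does not test why these genes fell further. Many immediate early genes have few exons, and the data do not separate exon number from gene function.

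A second hypothesis was not borne out. Transcripts of unannotated loci were proposed to fall less than annotated long noncoding RNAs, but the smallest difference of medians over the 3 cell types was −0.16 (0.38 in ectoderm, −0.16 in mesoderm, 0 in endoderm), so the sign was not shared.

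The 0 h levels left the labelled endoderm with collagen and smooth muscle RNAs beside endoderm ones: COL3A1 119 CPM, ACTA2 1050 CPM and PDGFRB 215 CPM next to CER1 157 ± 47 CPM and FOXA2 1.57 CPM. No single-cell data are in the series, so whether 1 cell held both sets is not known.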
